A study of Mus musculus with 6 samples.

How the data were processed

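RNA from forestomach epithelial sheets of 3 control and 3 Sox2 mutant mice had been hybridised to 2-colour Agilent mouse arrays, with the sample in Cy5 and Universal Mouse Reference RNA in Cy3, per the labels. The spot intensity values were deposited as the scanner software wrote them: mean signal, median local background and processed signal in each channel. Per the file headers the software was Agilent Feature Extraction 10.5.1.1, and 10.7.3.1 for control 3, whereas the submitters' processing notes give version 9.1. The processed intensity values had been background-subtracted and dye-normalized by that software, per the file headers. A table of log2 ratios deposited by the authors covers the same arrays; how they were normalized is not given in the sources used here. Set against the scanner files, its columns ran on a log2 scale in the direction of sample over reference, with slopes of 0.833 to 0.921 and column medians of 0.052, 0.06 and 0.026 for controls 1 to 3 and 0.042, 0.043 and 0.039 for mutants 1 to 3; centring stays unknown. Across probes the table's column for mutant 1 matched the scanner file of mutant 3 best (r = 0.963, against 0.865 with its own) and the column for mutant 3 that of mutant 1 (r = 0.957, against 0.868). Both are mutants, so comparisons of the groups do not depend on it, except where the replicate number enters as a block. The correlations of same-numbered arrays depend on it too. Which source carries the wrong number is not known, and statements on mutant 1 or mutant 3 follow the scanner files.

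From the scanner files, signals were corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3, with no weight given to control spots and to spots the software marked as outliers. These spots were then left out and spots of a probe averaged. Values are log2 of sample over reference, and differences are mutant minus control. A probe entered if it was well above background in the sample channel on at least 3 of the 6 arrays. A gene was represented by its probe with the highest mean sample-channel intensity, which gave 20080 genes, 7178 of them with several probes. Of 41174 probes, 33533 (81.4%) were named through the RefSeq gene table of assembly GRCm38.p6, 336 had no gene name and the rest kept the name of the files. Among 166 called genes with further probes, 31 of 234 further probes had the opposite sign and 2 of those passed the threshold. Coordinates are those of the files, whose genome build is not given in the sources used here.

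Groups were compared with lmFit and eBayes and Benjamini-Hochberg adjustment over genes, two-sided, with a threshold of 0.05. For a gene with no array of one group well above background, "at least" folds set the mean log2 sample channel of the other group, after loess and Aquantile, against the higher of the gene's own signal and the lowest signal well above background on each array. For a gene saturated on all arrays of one group, the measured means were used. Such bounds leave the reference channel out and are open to dye bias, since no dyes were swapped; the tests used the ratio, which was lower for each of these genes named, because their reference signal was higher in mutants too. This applied to 27 of the 573 called genes. Gene lists (36, with at least 5 members tested) were compared with camera at a preset correlation of 0.01 over 20005 genes with a value on every array. The number of arrays limits the precision: the fit has 4 residual degrees of freedom. No label says how the animals were housed or whether RNA was pooled, so p-values measure the spread between these samples, part of which may be technical.

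The comparison, the lists, the alternatives other than those named at the end and the rule for named genes were fixed before the data were examined. The rule names Sox2, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and that have a gene symbol, and for each list up to 4 members with the smallest p; members that did not pass are given with values only. Simulated data with the spread of the real arrays were tested over 20005 genes. In them limma recovered 36% of genes changed by 1 log2 unit and 75% of those changed by 2 units, with 7 false calls. Camera called 1 of 36 lists, the list that had been shifted. The simulated values were independent between genes and between arrays, whereas the correlation estimated within the mitosis list of the real arrays was 0.87. The simulation therefore does not show how either test behaves with correlated genes or near-identical arrays.

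Slide and scan day were taken from the labels and headers. Controls 1 and 2 shared slide 1, control 3 was on slide 2 and the mutants were on slide 3, so slide entered as a random block (duplicateCorrelation). Scan day 1 holds all arrays but control 3, so scan day entered as a block. Other alternatives concerned background correction, normalization, the deposited table, the filter on dim probes, probe choice, the variance model, the replicate number, the test and the threshold, and each array was left out in turn. Alternatives added after seeing the data averaged the near-identical arrays, used the glandular stomach signal as a covariate, took scan day as a block, left out genes on X and Y, or left out control 3 and mutant 1.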

Results

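Gene expression was measured in epithelial sheets of the mouse forestomach, the part of the stomach lined by a stratified squamous epithelium. The control mice carried K5-CreER, a tamoxifen-activated recombinase driven from the keratin 5 promoter of basal cells, and the mutant mice carried in addition a Sox2 transgene on both copies of the Rosa26 locus. Mice of 7 weeks received 2 doses of tamoxifen and were 12 weeks old per the labels, on a mixed strain background. There were 3 control and 3 mutant arrays, which the labels call biological replicates. On each of the 6 arrays the sample's RNA carried Cy5 and a common reference RNA from 11 mouse cell lines carried Cy3. Between 62.6% of the 41174 probes (control 3) and 76.2% (mutant 1) were well above background in the sample channel. The median sample signal was 4.78 times the background on control 3 and 11.9 to 13.2 times on the other arrays.

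The arrays were not equally distinct. Controls 1 and 2 differed by a scaled median absolute difference of 0.156 log2 units over the tested genes and mutants 2 and 3 by 0.104, against 0.326 to 0.733 for the remaining pairs. Over 245 probes printed in 10 spots each, the difference between mutants 2 and 3 was 3.18 times that expected from spot noise and the difference between controls 1 and 2 was 5.23 times. Noise between repeat hybridisations was not measured, so these ratios do not say whether the arrays of a pair came from separate animals. All 6 arrays were kept as separate samples, as labelled. If each near-identical pair came from one RNA, p-values in which they count as 2 samples are too small. Genes of the glandular stomach, the neighbouring columnar part of the organ, were lower on control 3 than on controls 1 and 2, by a median log2 difference of -3.24 over 31 genes. Control 3 was also the one array scanned on another day. No slide held arrays of both groups, so slide and genotype cannot be told apart.

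**Figure D1:**
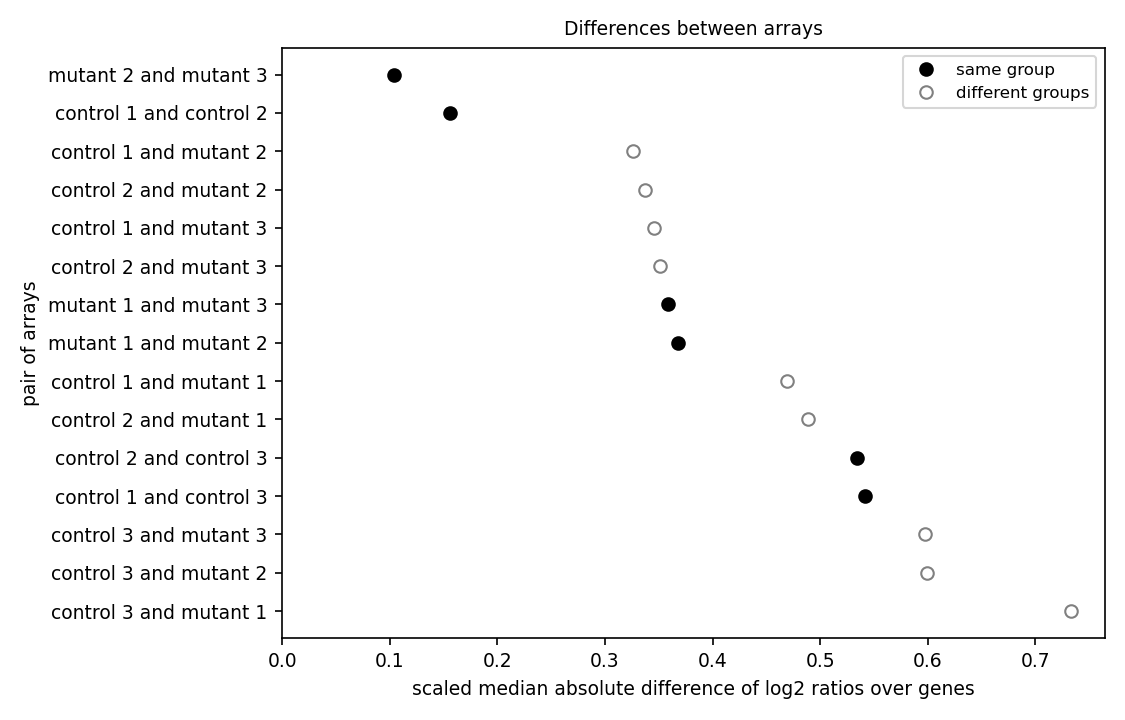
Each point is one pair of arrays, placed on the horizontal axis by the scaled median absolute difference of their log2 ratios over the tested genes; filled points are pairs within a group and open points pairs across groups. Mutants 2 and 3 (0.104) and controls 1 and 2 (0.156) lie apart from all other pairs, which start at 0.326.

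The targeted gene was examined first. Sox2, a transcription factor of foregut progenitors, had a log2 ratio of 6.24 ± 0.15 (SD, n = 3) in controls and 5.82 ± 0.14 (SD, n = 3) in mutants. The difference of -0.43 (SE 0.14) did not pass the threshold (limma, adjusted p = 0.142), and an exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. The array holds 1 Sox2 probe, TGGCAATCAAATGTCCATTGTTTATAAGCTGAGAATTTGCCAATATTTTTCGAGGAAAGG, placed by the files on chromosome 3 from 34550773 to 34550832, in a genome build not given in the sources used here. By the files it starts at position 1846 of the transcript, which lies past the coding part, and the labels do not say whether the transgene holds this part, so the probe does not check the transgene. Over the alternatives the difference ran from -0.79, with the scanner software's processed signals, to 0.10. Scaling the arrays to one spread turned the sign to 0.10, and array weights brought the adjusted p to 0.0316 with a difference of -0.20. Over all alternatives the adjusted p ranged from 0.0316 to 0.824. The transcript of the locus that carries the insertion, Gt(ROSA)26Sor (chromosome 6, 113021054 to 113021113 in the files), fell from a log2 ratio of 1.05 ± 0.23 (SD, n = 3) in controls to -2.65 ± 0.08 (SD, n = 3) in mutants, a 12.9-fold difference with an adjusted p of 0.00115.

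Among genes past the threshold with a gene symbol, S100a8, a subunit of the neutrophil and keratinocyte alarmin calprotectin, rose most in the ratio, 231-fold. Its log2 difference in the mutant forestomach was 7.85 (SE 0.46, limma, adjusted p = 0.00337), from -1.82 ± 0.93 to 6.04 ± 0.32 (SD, n = 3 each). Over the alternatives that difference ran from 7.19 to 9.47. The beta-defensins Defb6 and Defb3 rose 22.8-fold and 22.4-fold (log2 differences 4.51 and 4.49, or 3.90 and 3.67 without control 3), and the secreted lectin Reg1 rose 35.9-fold (5.17, or 6.03 without mutant 1). The lectin Reg3b, the cytokine Il19 and the defensin-related Defa-rs2 were not well above background on any control array. In the sample channel alone they were at least 74.7-fold, 174-fold and 23.2-fold higher in mutants, against 37.1-fold, 19.3-fold and 15.6-fold in the ratio that was tested. Single arrays moved these bounds: Il19 was at least 79.7-fold higher without mutant 1 and 301-fold without mutant 2, Reg3b 141-fold without mutant 1 and 43.1-fold without mutant 2, and Defa-rs2 34.9-fold without mutant 1. The ratio of Il19 was held down by the reference channel, whose signal was 11.2 times as high on mutant as on control arrays, and its log2 difference ran from 4.15 to 7.80 over the alternatives, the highest in the sample channel alone. In all, 573 of 20080 genes passed an adjusted p of 0.05 in limma, 286 higher and 287 lower in mutants, and 352 of them differed at least 2-fold (194 higher, 158 lower). That count depended on how the near-identical arrays were counted. With each such pair averaged, an alternative chosen after seeing the data that leaves 2 values per group, limma called 0 genes, with 2141 at an unadjusted p under 0.05. With the slide as a random block it called 4, namely Il19, Uox, Gt(ROSA)26Sor and S100a8, and without mutant 2 or without mutant 3 it called 20. Without control 1 the count was 57 and without control 2 it was 44. Without control 3 it was 1452, which is also the count within the one scan day that holds both groups, and with scan day as a block it was 1469. Without both control 3 and mutant 1 the count was 7396. That fit sets the near-identical control pair against the near-identical mutant pair, each counted as 2 samples. The pairs also differ in slide and in sex-linked genes. With array weights, which gave control 3 a weight of 0.0762 and favoured control 2 (5.19) and mutant 3 (7.73), the count was 11391. The 3 mutant values lay wholly above or below the 3 control values for each of the 573 called genes and for 38.1% of all genes, where chance gives 10% if the 6 arrays are independent and 33.3% if each near-identical pair counts once.

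Next by size in the ratio, Uox, the urate oxidase of purine breakdown, rose 38.3-fold (log2 difference 5.26, SE 0.17, limma, adjusted p = 0.000442). It was well above background on 2 of the 3 control arrays. A second Uox probe gave a log2 difference of 4.50. In the sample channel after loess and Aquantile Uox rose 584-fold, more than S100a8 at 536-fold. Cdkn1c and Sprr2h, outside the 10 largest rises in the ratio, rose 140-fold and 122-fold there. Over the alternatives the Uox difference ran from 4.84 to 9.24, the highest in the sample channel alone, since the Uox signal in the reference channel was 15.3 times as high on mutant arrays. Shisa3, an antagonist of Wnt and FGF receptor maturation, rose 21.8-fold and the membrane protein gene Itm2a rose 15.5-fold. Defb6, Reg1 and Shisa3 were each well above background on 2 of 3 control arrays.

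The largest fall was that of Trim12a, a TRIM-family gene, which was 28.0-fold lower in mutants (log2 difference -4.81, SE 0.32, adjusted p = 0.00373). Its second probe fell by 1.41 on the log2 scale. Ttpa, which encodes the alpha-tocopherol transfer protein, fell 5.24-fold, with a second probe at -2.40. The deubiquitinase family gene Usp53 fell 6.12-fold on the probe tested, whereas its 3 other probes stood at 0.41, -0.90 and 0.67 with no call. Zinc finger gene Zfp933 fell 4.76-fold on 1 of 3 probes, the others standing at 0.04 and -0.33. The proteoglycan gene Cspg5 fell 6.01-fold, its second probe standing at -0.97 with no call (adjusted p = 0.0934), Crtac1 5.53-fold, the neurotrophin receptor gene Ntrk3 5.28-fold, with a second probe at -1.54, Tmem145 4.77-fold and the peptide and histidine transporter gene Slc15a3 4.73-fold. Adjusted p-values of these 9 falls and of the rises above ran up to 0.0455. Under averaging of the near-identical pairs none of them passed. Every direction was kept, which was fixed in advance since their groups do not overlap.

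**Figure D2:**
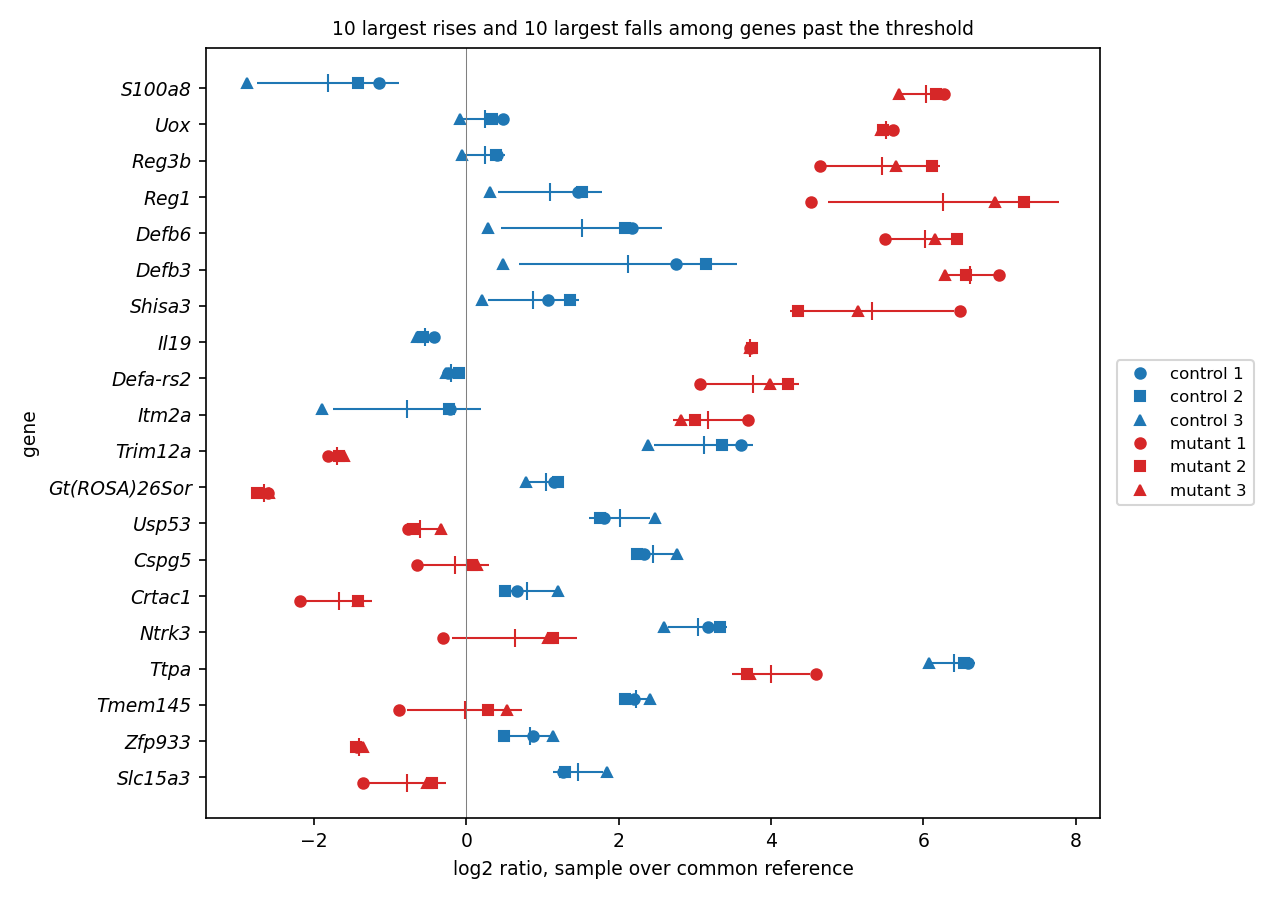
Log2 ratio of sample over common reference on each array (horizontal axis) for the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold; circles, squares and triangles are replicates 1, 2 and 3, vertical ticks are group means and horizontal bars are SDs over 3 arrays. For S100a8 the control mean is -1.82 and the mutant mean 6.04. The rule for naming genes took only those whose groups do not overlap, so the gap between groups in all 20 genes follows from the choice.

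Proliferation genes were higher in mutants as a group. All 43 measured members of the mitosis and G2/M list had a positive difference, with a median of 1.16 log2 units, and all 41 of the DNA replication and G1/S list but 2 did, with a median of 0.67. Both lists were called by camera with the preset correlation of 0.01 (adjusted p = 4.39e-16 and 1.73e-09). Neither was called with an estimated correlation, which was 0.87 and 0.59 (adjusted p = 0.899 for each). With the preset correlation each list was called in 7 of the 10 splits of the arrays into 3 and 3, the real split included. The mitotic kinesin gene Kif4 rose 2.33-fold (log2 difference 1.22, SE 0.16, adjusted p = 0.0213), the primase gene Prim1 1.57-fold and the flap endonuclease gene Fen1 2.02-fold, and no further member passed over all genes. Cdc20, an activator of the anaphase-promoting complex, stood at 1.51 (adjusted p = 0.0626) and passed without control 3 (1.19), and the kinase gene Nek2 at 1.02 and the ribonucleotide reductase gene Rrm1 at 1.44 likewise did not pass. Adjusted over the list alone, 41 mitosis genes and 13 replication genes passed. Within the scan day that holds both groups the medians were 0.82 and 0.52. Control 3 minus the mean of controls 1 and 2 had a median of -1.12 on the mitosis list and -0.45 on the replication list.

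Squamous differentiation genes were lower as a group. In the list of differentiation and cornified envelope genes 41 of 45 members had a negative difference, with a median of -0.73 (camera, adjusted p = 6.38e-08; adjusted p = 0.899 with an estimated correlation). No member passed over all genes or when adjusted over the list alone. The envelope precursor gene Ivl stood at -1.26 (SE 0.26, limma, adjusted p = 0.0611) and the filaggrin family gene Flg2 at -2.16 (SE 0.46, adjusted p = 0.0664). Tchh, the trichohyalin gene, stood at 2.24 (SE 0.52, adjusted p = 0.0799), in a range over the alternatives of 1.41 to 2.66. Mutant 1 weighed on Tchh, with a raw sample signal of 15055 against 4007 and 4378 on mutants 2 and 3. In the reference channel Ivl and Flg2 were lower in mutants too, so that their sample-channel differences were larger, at -3.08 and -3.59. Flg2 passed without mutant 1 (-1.60, limma, adjusted p = 0.0122). Over the alternatives its difference ran from -3.66 to -0.33 and its adjusted p from 8.4e-05 to 0.645. The difference of Ivl ran from -3.11 to -0.81 and its adjusted p from 0.000163 to 0.6. In the sample channel alone, quantile-normalized, the list was called lower with a smaller median of -0.31 (adjusted p = 0.0293), 33 of 45 members being negative, and after loess and Aquantile the sample-channel median was -0.56. On at least 1 array 9 of the 45 members were saturated, and without them the median was -0.68 in the ratio and -0.61 in the sample channel after loess and Aquantile. The median was -0.40 within the scan day that holds both groups, and control 3 minus the mean of controls 1 and 2 had a median of 0.90. Basal layer genes had a median of -0.03 and a mean of 0.08 over 20 members with none called, the basal keratin gene Krt15 standing at -0.56. In the sample channel alone, quantile-normalized, the basal list had a median of 0.29 with 15 of 20 members positive, and was not called either (camera, adjusted p = 0.341).

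For stress and defence genes of the epidermis the answer depended on the channel. In the ratio, the list of stress keratins and activated epidermal genes was not called (median 0.20, or 0.36 with S100a9, saturated in all mutants, at its bound; adjusted p = 0.316). In the sample channel alone it was called higher (median 2.54, adjusted p = 3.28e-12), with 18 of 21 members positive and 9 called. After loess and Aquantile its median was 2.23 in the sample channel and 1.56 in the reference channel, each the highest of the 36 lists. Why the reference signal of these genes differed between the groups was not tested. Of 21 members, S100a8, Defb3 and the small proline-rich genes Sprr2f (4.96-fold) and Sprr2h (5.09-fold) rose in the ratio. Over the alternatives the log2 difference of Sprr2f ran from 1.14 (processed signals, adjusted p = 0.102, in a range of 7.1e-06 to 0.318) to 6.28, and that of Sprr2h from 1.96 to 7.04, each highest in the sample channel alone. Their reference signals were 15.8 and 24.0 times as high on mutant arrays. In the ratio, 5 members rose when adjusted over the list alone and 1 fell, against 15 and 0 in the sample channel alone.

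Of the immune lists, 3 were called higher in mutants, while the interferon (median 0.28, adjusted p = 0.133) and lymphocyte (median 0.18, adjusted p = 0.761) lists were not. The 3 calls came from camera with the preset correlation (adjusted p = 0.0015, 0.0021 and 0.00294 for the macrophage, chemokine and neutrophil lists), and none passed with an estimated correlation (adjusted p = 0.899 each). The macrophage and dendritic cell list had a median of 0.73, with 20 of 26 members positive, and Cd68, a lysosomal protein gene of macrophages, rose 2.81-fold while the receptor gene Csf1r rose 1.68-fold, its other 2 probes standing at 0.56 and 0.04 with no call. Chemokine and cytokine genes had a median of 0.59 over 28 members. In that list Ccl20, the ligand of the chemokine receptor CCR6, rose 12.2-fold and Il1b rose 8.38-fold. Of the 17 neutrophil, mast cell and eosinophil genes, 16 were positive, with a median of 0.88, and Retnlg, a resistin-like gene of neutrophils, was at least 28.9-fold higher in the sample channel and 12.9-fold in the ratio, being not well above background on any control array. Ngp and Csf3r, also not well above background in controls, did not pass (at least 5.53-fold and 4.24-fold higher in the sample channel, 4.15-fold and 3.16-fold in the ratio, adjusted p = 0.103 and 0.112). Mutant 1 weighed on all 3: without it the bounds were 13.4-fold for Retnlg, 2.17-fold for Ngp and 2.38-fold for Csf3r, and the ratios 10.2-fold, 2.62-fold and 2.15-fold. The bounds of Retnlg and Ngp were 43.3-fold and 8.91-fold without mutant 3, and that of Ngp 8.73-fold without mutant 2. Adjusted over the list alone, 3 macrophage genes, 4 chemokine genes and 4 genes of the neutrophil, mast cell and eosinophil list rose. That last list does not isolate neutrophils: its mast cell receptor gene Fcer1a stood at 1.55 and did not pass over all genes. Without control 3 the neutrophil list was lost (median 0.22, adjusted p = 0.388), as it was without mutant 2 (median 0.44, adjusted p = 0.115), and the macrophage and chemokine medians were 0.49 and 0.33 without control 3. Without both control 3 and mutant 1 camera called neither the macrophage (median 0.14, adjusted p = 0.0719) nor the neutrophil list (median 0.22, adjusted p = 0.502). Control 3 minus the mean of controls 1 and 2 had medians of -0.43, -0.59 and -1.52 on the macrophage, chemokine and neutrophil lists.

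Matrix and metabolic lists, 5 in all, were called by camera with the preset correlation, and none of them with an estimated correlation (adjusted p = 0.899 each). The list of epithelial-mesenchymal transition and matrix remodelling genes had a median of 0.67 and 1 member called, the epithelial metalloproteinase gene Mmp7, which rose 3.43-fold and was well above background on 1 of 3 control arrays. Fibroblast genes had a median of 0.70 with no member called, C3 standing at 1.40 (0.89 without control 3, where it passed) and Bgn at 0.50. A second C3 probe stood at -0.18. Among glycolysis and hypoxia genes (median 0.48), the hypoxia-responsive gene Ndrg1 rose 3.19-fold, and adjusted over the list alone 10 members rose and 2 fell. Genes of Nrf2 and glutathione metabolism had a median of -0.39, and 3 members fell when adjusted over the list alone. Among these, the glutathione transferase gene Gstm1 fell 3.40-fold, its second probe standing at -1.24 with no call. In the sample channel after loess and Aquantile Gstm1 fell 1.98-fold, its reference signal being 1.71 times as high on mutant arrays. Over the alternatives its log2 difference ran from -2.01 to -0.70. Ribosome biogenesis genes had a median of 0.24 and no member called. The adjusted p-values with the preset correlation were 0.000259, 0.00151, 0.00047, 0.00418 and 0.0198. In the sample channel alone the Nrf2 and ribosome lists did not pass (medians -0.07 and 0.22, adjusted p = 0.661 and 0.0978). Within the scan day that holds both groups the medians were 0.36, 0.26, 0.47, -0.23 and 0.17, and the last 2 lists did not pass there (adjusted p = 0.12 and 0.113). Ribosome biogenesis did not pass without mutant 1 either (median 0.14, adjusted p = 0.382). Without both control 3 and mutant 1 camera called neither the fibroblast (median 0.21, adjusted p = 0.0719), the Nrf2 (-0.16, adjusted p = 0.159) nor the ribosome list (0.0050, adjusted p = 0.787). Control 3 minus the mean of controls 1 and 2 had medians of -0.59, -1.32, -0.35, 0.50 and -0.21 on the 5 lists.

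Camera with the preset correlation called 11 of 36 lists in all, 9 higher and 2 lower in mutants. In the sample channel alone it called 10, 9 of them shared. With the correlation estimated it called 0, with 0 at an unadjusted p under 0.05, and fry called 0, with 4 at an unadjusted p under 0.05.

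**Figure D3:**
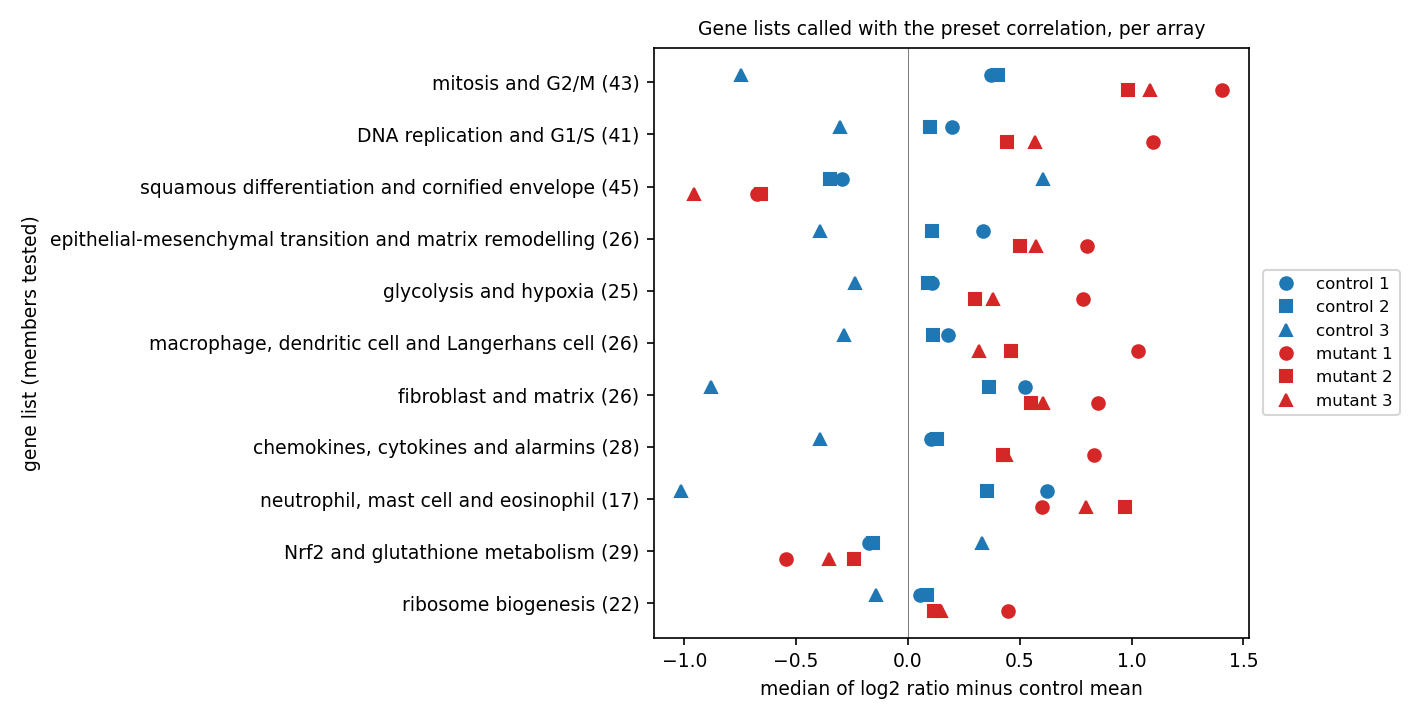
Median over the members of each called gene list of the log2 ratio minus the control mean (horizontal axis), one point per array; circles, squares and triangles are replicates 1, 2 and 3, and the number of members tested stands in brackets. On the mitosis list the mutants lie at 0.98 to 1.40, above controls 1 and 2 at 0.37 and 0.40 and control 3 at -0.75.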

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

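Genes whose reference signal was higher in mutants were looked for after the values were seen. The reference channel, which holds the same RNA on every array, was outside the comparison of groups. Among the genes named, its signal was at least 2-fold higher on mutant than on control arrays for Sprr2h (24.0 times), Sprr2f (15.8), Uox (15.3), Cdkn1c (12.9), Il19 (11.2), Retnlg (2.42), S100a8 (2.32), Reg3b (2.22) and Lce3c (2.12), and for S100a9 (4.58), the partner subunit of S100a8. It was 3.53 times lower for Ivl, 2.69 times lower for Flg2 and 2.39 times lower for Hspa1b. Of these, Ivl passed the threshold in the reference channel (adjusted p = 0.0404) and the others did not; over all genes 28 of 20080 did in limma, 2 of them among the 573 called in the ratio. S100a9 was saturated in the sample channel on all 3 mutant arrays and at least 4.69-fold higher than in controls, so its ratio carries no fold change.

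The reference moved with the sample. Of 37 genes at least 16-fold higher in the sample channel of mutants, 26 were at least 2-fold higher in the reference channel and 0 were 2-fold lower, with a median over the 37 of 2.05 log2 units. Of 18415 genes that changed under 2-fold in the sample channel, 22 differed at least 2-fold in the reference in the direction of the sample and 2 in the opposite one. On mutants 1, 2 and 3 the raw reference signal was 6.64%, 6.89% and 6.83% of the sample signal for Il19, 1.77%, 2.00% and 1.94% for Uox and 9.98%, 9.79% and 10.6% for Sprr2h. The ratio of Il19 therefore had an SD of 0.015 over the mutants, where its sample channel had one of 2.00. For Uox these SDs were 0.080 and 0.94. The ratio of these genes thus gave a smaller fold and a smaller spread over mutants than the sample channel, and their adjusted p of 0.000231 and 0.000442 and their calls with slide as a random block come from the ratio. In the sample channel alone the adjusted p was 0.0261 for Il19 and 0.006 for Uox, in a range over the alternatives of 2.68e-08 to 0.0848 for each. Of the 573 called genes, 21 differed 2-fold in the reference, each in the direction of the sample, and 552 did not. The cause was not tested.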

How the results depend on the processing

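The averaged pairs, the glandular covariate, the scan-day block, the removal of X and Y genes and the removal of control 3 with mutant 1 were chosen after seeing the data; the other alternatives were planned. Against 573 genes, the count was 326 with the scanner software's processed signals, 269 with median centring, 311 with the sample channel alone, 183 with an ordinary per-gene test, 127 with the replicate block, 4 with slide as a random block, 11391 with array weights, 59 at a threshold of 0.01 and 1567 at 0.1. It was 0 with near-identical arrays averaged (limma, 2141 at an unadjusted p under 0.05), 1818 with the glandular covariate and 1469 with scan day as a block. It was 7396 without control 3 and mutant 1, where only the near-identical pairs were compared, each counted as 2 samples. Leaving out one array gave 20 to 1452 genes: 57 without control 1, 44 without control 2, 1452 without control 3, 517 without mutant 1, 20 without mutant 2 and 20 without mutant 3. It stayed within 1.5 times under the remaining settings, of which Aquantile leaves ratios as they are by construction. Array weights gave control 3 a weight of 0.0762 and mutant 3 one of 7.73. The share of calls that were higher was 49.9%. It was 75% of the 4 calls with slide as a random block, 70.9% with the replicate block, 67.8% at a threshold of 0.01, 44.6% with scan day as a block and 56.1% with processed signals. Leaving out one array gave 44.9% (without control 3) to 70% (without mutant 3), with 68.4% without control 1 and 63.6% without control 2. With the replicate block 90 were higher and 37 lower; the correlations of same-numbered arrays' deviations were 0.00448, 0.0202 and 0.124, so the numbers were not taken as pairing, and the block ended no list call. The Sox2 difference of -0.43 reversed to 0.10 with scaling and passed with array weights at -0.20 (adjusted p = 0.0316). It was -0.79 with processed signals and -0.65 with the sample channel alone. Leaving out one array gave -0.50 to -0.35, and adjusted p ranged from 0.0316 to 0.824. Lists called were 11, against 10 in the sample channel alone (9 shared, with Nrf2 and ribosome biogenesis lost and stress keratins gained) and 7 with array weights. They were 0 with an estimated correlation, 0 with fry (4 at an unadjusted p under 0.05) and 10 to 14 when one array was left out. Camera was not run with slide as a random block. Of the 11 calls, scaling lost 2, the mean of all probes of a gene 1 and the filter on all 6 arrays 1. The scan-day block lost 3 and the removal of control 3 with mutant 1 lost 5. Of 41 called genes named, none reversed in 1035 refits and 342 refits lost the call. The groups do not overlap for any called gene. Refits that only leave out or average arrays therefore could not reverse a gene on the same probe, and say nothing on its direction. Among these losses were 41 with averaged pairs, 37 with slide as a random block, 31 with the ordinary per-gene test and 18 with the replicate block. Leaving out one array lost 32 without mutant 2, 32 without mutant 3, 30 without control 1 and 30 without control 2. Of the uncalled genes named, Lce3c reversed to 0.25 with the sample channel alone, a value that cannot be read exactly since its probe was saturated on 2 of 3 mutant arrays, and Sox6 to 0.036 with scaling. The cause was not tested for the other moves; leaving out or averaging arrays lowers the number of samples. Signal over background, 4.78 on control 3, limits what that array shows of dim genes.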

Other observations

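Outside the lists that were called, several regulators changed singly. Cdkn1c, an inhibitor of cyclin-dependent kinases, rose 10.9-fold (log2 difference 3.44, SE 0.23, limma adjusted p = 0.00385), in a range over the alternatives of 3.14 to 7.32, the highest in the sample channel alone. The EGF receptor ligand gene Hbegf rose 3.05-fold and the growth factor gene Fgf1 fell 3.60-fold, being well above background on 1 of 3 mutant arrays, with a second probe at -0.29. The RNA-binding protein gene Lin28b rose 1.79-fold, the immediate early gene Egr2 fell 2.62-fold and the heat shock gene Hspa1a fell 2.41-fold (second probe -1.16, not called). The interferon-induced gene Xaf1 fell 1.79-fold and the ciliary gene Tekt1 fell 2.03-fold. Over the alternatives the log2 difference ran from -2.93 to -1.07 for Fgf1, from 0.73 to 2.04 for Lin28b and from -1.90 to -0.87 for Tekt1. With near-identical arrays averaged none of the genes in this paragraph passed.

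The remaining 25 lists were not called. Their medians were 0.28 for interferon response, -0.23 for respiratory epithelium, -0.22 for cholesterol and lipid synthesis, 0.25 for JAK-STAT3, 0.26 for endothelium, -0.14 for Wnt, -0.15 for junctions, 0.08 for oxidative phosphorylation, -0.13 for muscle, -0.06 for intestine, -0.0030 for heat shock, -0.10 for Notch, 0.08 for BMP, TGF-beta and Hedgehog, -0.09 for cell cycle inhibitors, 0.05 for steroid hormone and sex-linked genes, 0.11 for immediate early genes, 0.34 for glandular stomach, 0.18 for lymphocytes, -0.11 for adipocyte, erythroid and pancreas genes, 0.04 for pluripotency factors, 0.03 for neural genes, 0.07 for the SOX family and 0.02 for EGFR and FGF ligands. The means had the other sign for the intestine (0.66), adipocyte (0.10), cell cycle inhibitor (0.06), steroid hormone and sex-linked (-0.87), neural (-0.0035) and EGFR and FGF (-0.0050) lists. Several of these depended on single arrays. Without control 3 the median changed sign in 10 of the 25, the interferon list (-0.0020), cholesterol (0.02), stress keratins (-0.06) and endothelium (-0.22, adjusted p = 0.584) among them. Camera then called glandular stomach (-0.63, adjusted p = 0.0102), muscle (-0.53, adjusted p = 0.0354) and Wnt (-0.31, adjusted p = 0.0354) lower. Without both control 3 and mutant 1 it called glandular stomach (-0.20) and endothelium (-0.34) lower, each at 0.0356. With averaged pairs it called interferon higher (0.27, adjusted p = 0.0359), endothelium higher (0.54, adjusted p = 0.0194) and cholesterol lower (-0.29, adjusted p = 0.0261), and with the glandular covariate interferon higher (0.28, adjusted p = 0.0153). Stress keratins and basal genes are given above. Xist stood at 1.28 and 1.33 on mutants 2 and 3 and between -7.03 and -3.93 on the other 4 arrays, and the Y-linked gene Ddx3y at -4.74 and -4.72 on mutants 2 and 3 and between 1.04 and 1.33 on the others.

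Of the tests in the next paragraphs, those on the near-identical arrays, on control 3, on glandular tissue, on Gt(ROSA)26Sor and on the differentiation list in the reference channel were chosen after the result was seen; the splits and the mitosis list in the reference channel were not. The real split called 573 genes and the highest of the other splits 0 (limma; 29 to 1425 at an unadjusted p under 0.05), so 1 of 10 splits gave as many; 10 splits are too few for a share under 0.05. For the lists, 7 of 10 splits gave as many as the real 11, and the highest other gave 15, with the same limit. The mitosis and replication lists were each called in 7 of 10 splits and the differentiation list in 8, the real split included. Their medians were largest in size in the real split (1.16, 0.67 and -0.73), the other splits reaching absolute medians of 0.81, 0.55 and 0.57. The split of controls 1 and 2 with mutant 1 against the rest, which keeps both near-identical pairs whole, called 0 genes, with 1425 at an unadjusted p under 0.05 against 4807 for the real split. No split but this and the real split keeps both pairs whole. The others part at least 1 pair, which widens the spread within a side, so their 0 called genes say little.

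A first pattern is the near-identical arrays. Sharing a slide was not enough for it. Mutant 1 shares the slide of mutants 2 and 3, and its highest correlation with them was 0.921 across genes, against 0.995 between those 2. The slide of controls 1 and 2 held no further array of this series, and mutant 1 differs from mutants 2 and 3 in sex-linked genes. A part played by the slide therefore stays open. One RNA hybridised more than once stays possible for each pair. Mutants 2 and 3 differed by 3.18 times the spot noise and controls 1 and 2 by 5.23 times, but a repeat hybridisation adds noise that no array here measures. Ddx3y differed by 0.075 and 0.027 log2 units within the control and mutant pairs, and Xist by 2.22 and 0.054. The control pair was thus less alike than the mutant pair. Separate animals of like tissue content, as labelled, cannot be told apart from one RNA hybridised more than once.

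A second pattern is the higher cell cycle and lower differentiation genes. Control 3 alone would leave the mitosis median near 0 without that array, but it was 0.82. The list was still called then, though with the preset correlation and with the near-identical controls 1 and 2 counted as 2 samples. Glandular tissue as the whole source was predicted to bring the median near 0 under the covariate. It was 1.15, while the count of called genes went from 573 to 1818. The glandular signal was 3.44, 3.33 and 0.28 on controls 1 to 3 and 1.41, 3.00 and 2.70 on mutants 1 to 3. Its average was nearly the same in both groups, so the covariate could hardly move a group difference and cannot decide on glandular tissue. Of the 31 glandular genes, 2 stand in another list. A shift in the reference channel is argued against by its median of -0.054 on the mitosis list, but not for the differentiation list, where the reference median was 0.19 and the sample-channel median -0.56 on that scale and -0.31 after quantile normalization, against -0.73 in the ratio, so it may account for a part whose size depends on the normalization. What stays open, untested, is an effect of the transgene, the slide, sex or tissue content, glandular tissue included. No slide holds both groups, and camera was not run with slide as a block. Mutants 2 and 3 carry a female pattern of sex-linked genes, and mutant 1 and all controls a male pattern. The labels give no sex, and by this pattern sex is partly confounded with genotype. With the estimated correlation, which is between genes of the list, the list call is lost. The near-identical arrays also mean that the hypothesis of more proliferation in mutants may rest on few independent samples.

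The last pattern is where called genes lie. Within 20 Mb of Gt(ROSA)26Sor 19 of 308 genes were called (6.17%, against 2.84% of all), and 3.73% of windows around other tested genes held as high a share; within 2, 5 and 10 Mb, 19.2%, 13.7% and 8.87% of windows did. These counts include Gt(ROSA)26Sor itself, which is called, whereas the other windows are centred on any tested gene, called or not. Within 2 Mb 2 of 40 genes were called, Gt(ROSA)26Sor among them. The comparison thus leans towards a high share. DNA of another strain around the insertion may contribute, and the widths differ, so it cannot be told apart from ordinary clustering. On chromosome 4, 12 of 78 genes between 145 and 150 Mb of the files' coordinates were called, Zfp933 among them, the smallest p of 457 bins tested (hypergeometric, adjusted p = 0.000893, genes not being independent). On chromosome 8, 5 of 18 genes between 15 and 20 Mb, Defb3 and Defb6 among them (adjusted p = 0.0263), and 5 of 21 between 40 and 45 Mb (adjusted p = 0.0388) were called too.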
